A study of Homo sapiens with 2 samples.

How the data were processed

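The series profiled mature miRNAs by SYBR Green quantitative PCR in 2 samples of primary human mammary epithelial cells, bought commercially and grown in mammary epithelial medium. One sample was exposed to an active Jagged1 peptide and the other to a control peptide, for 24 h at 40 mM, the concentration the labels state. That is very high for a peptide, so its unit is in doubt and the dose should be read with that limit. Jagged1 is a ligand of the Notch receptors. Per the labels' protocols, total RNA was extracted with a kit and treated with DNase, and assays for mature miRNAs were run on a commercial human PCR array. The reverse transcription, the instrument, the baseline and threshold settings and the number of wells behind each value are not given in the sources used here. In the deposited tables the control column is headed DMSO, whereas the labels name a control peptide. It was taken as the control sample because it is the denominator of the deposited Jagged1 ratio and the series has 1 other sample. Whether the control cells received the peptide, the solvent or both stays open.

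The array layout holds 1008 assays on 12 plates of 84, and 905 assays have a value in both samples. The other 103 assays are listed with no value in either sample and were not analysed here. Small RNA reference assays and reverse transcription or PCR controls were not analysed here. The first of 3 deposited tables gives the authors' non-normalized cycle threshold (Ct), which was handled as a score in cycles because no header names its unit. Ct falls by 1 for each doubling of template at full PCR efficiency, and the table carries 1 decimal. The second table, deposited as normalized, holds a ratio to a reference. Comparing it with the first showed that the authors' values equal 2 to the power of 20 minus Ct within 0.05 cycles for 899 of 905 assays in the control sample and 898 of 905 in the Jagged1 sample. The reference was therefore equivalent to the same Ct of 20 in both samples. Whether measured RNAs gave this value, and which, is not given in the sources used here. With an equal reference, the normalized table carries no correction for RNA input that differs between the samples. The third table is the authors' fold ratio of Jagged1 over control. It matched the quotient of the normalized columns within 0.05 on the log2 scale for 899 assays and differed for 6.

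From these tables the log2 ratio of Jagged1 over control was computed per assay from the authors' normalized values, with no pseudocount. A log2 ratio of 1 is a 2-fold difference. The assays counted for the main comparison had a mean raw Ct below 30 and a raw Ct below 35 in both samples (489 assays). An assay was counted as higher or lower from a 2-fold difference, with a tolerance of 0.001 on the log2 scale. A Ct below 35 was taken as detected. The value 35 was treated as a ceiling, since 160 assays carry it in both samples.

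There is 1 sample per treatment, so no SD, standard error or p-value between treatments exists, and every difference compares these 2 samples and not the conditions. No repeated wells were analysed here, so the technical error could not be measured either. Lists of miRNA families, genomic clusters, pathways and cell type markers were fixed before the data were examined, as were the filter, the threshold and the rule for named miRNAs. That rule took the counted assays at least 2-fold apart (at most 12 per direction), the 5 assays of lowest mean Ct, up to 4 members of largest absolute ratio per list among assays below Ct 35 in both samples, and every such member of lists with 1 or 2 stems. It also named miRNAs detected below Ct 30 in one sample and at 35 or above in the other, of which there were 0 in each direction. A list member is an assay named by its stem alone or with its arm suffix, with current names for older stems. The tables use no star names, so arms named by stem and suffix alone count as members, and the planned comparison with star strands added was not a separate setting. Arms whose name also carries a locus number, such as let-7f-1-3p, are not members under this rule. Adding them, which brings 9 counted assays into 8 lists, was an alternative chosen after the data were seen. For lists with at least 3 counted members, the median log2 ratio was placed among 10000 random lists of the same size matched on deciles of mean Ct. This percentile describes these 2 samples and is not a test of the treatment. Some assays share every value with an assay of another name, such as miR-195-3p and miR-1278. Members of different lists do so as well, such as miR-449b-5p and miR-154-5p, or miR-432-5p and miR-508-5p. List members may therefore not all be separate measurements.

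The alternatives were other normalizations (median of all counted assays at 0, median of each plate at 0, mean of the 50 assays of lowest Ct, raw Ct, the authors' fold table), other Ct limits and other fold thresholds. Normalization to reference RNA wells, and leaving out each reference RNA in turn, were not run, since no such values were analysed here. The counting and list steps were checked on simulated ratios for the 489 assays with an SD of 0.3 for unchanged assays. Of 50 assays simulated at each fold, 100% were counted at 3-fold, 52% at 2-fold and 16% at 1.5-fold. The simulated SD was chosen and is below the SD of 0.40 across the real ratios, so this checks the counting step and gives no rate of false counts for these data. Of 100 unshifted random lists, 5 fell outside the central 95% of random medians. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The genes next to each other in the genome were taken from a RefSeq gene table of GRCh38.p14, used for names and neighbours only. Of all assays, 902 matched 1 gene in it and 106 were not placed. The files name no genome build, so no coordinates are given.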

Results

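Mature miRNAs were measured in primary human mammary epithelial cells after 24 h with an active Jagged1 peptide or a control peptide, with 1 sample per treatment. Of 1008 assays, 905 had a Ct in both samples. A Ct below 35 was reached by 741 assays in the control sample and by 734 in the Jagged1 sample. Ct ran from 13.2 to 37 in the control sample and from 13.2 to 37.4 in the Jagged1 sample, with a median of 29 in each. The 5 assays of lowest mean Ct were miR-196a-3p, miR-138-1-3p, miR-3140-3p, miR-1263 and miR-1322. Their log2 ratios ran from -0.46 for miR-3140-3p to 0.13 for miR-1322. Ct depends on the efficiency of each assay, so a lower Ct of one miRNA than of another is not read as a higher level. No value has a replicate, and all ratios below compare the Jagged1 sample with the control sample without an error estimate.

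The main comparison asked which miRNAs differ after Jagged1, a Notch ligand, as the series title states. Among the 489 assays with a mean Ct below 30, miR-181a-5p and miR-17-3p were at least 2-fold higher with Jagged1, and let-7c-5p and miR-34a-5p were 2-fold lower. miR-181a-5p, known from lymphocyte development, had a Ct of 30 in the control and 27.5 with Jagged1, which is 5.66-fold higher. miR-17-3p comes from the precursor of miR-17 in the MYC-induced miR-17 cluster and was 3.73-fold higher (Ct 24.5 and 22.6). let-7c-5p, of the differentiation-associated let-7 family, had a Ct of 23 and 24. miR-34a-5p, a p53-induced miRNA that represses NOTCH1 and JAG1, had a Ct of 26 and 27. Both stood at a log2 ratio of -1, on the threshold itself. Both have whole-number Ct values in both samples, which holds for 33 of 734 assays, and miR-181a-5p has one in the control. Without assays that have a whole-number Ct, a setting chosen after the data were seen, 1 miRNA was counted as higher (miR-17-3p) and 0 as lower.

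The largest difference among all 905 assays with a value was in miR-205-5p, a miRNA enriched in basal and stratified epithelium that represses ZEB1 and ZEB2. Its Ct was 28.5 in the control and 31.6 with Jagged1, a log2 ratio of -3.07 or an 8.4-fold lower level. Its mean Ct lies just over the limit of 30, so it was outside the 489 counted assays and was named as a member of the epithelial list. Whether this assay or any other measures the arm it names was not established. miR-200c-3p, of the ZEB-repressing miR-200 family, was also outside that set and was 2.14-fold lower (Ct 30 and 31.1, log2 ratio -1.10). With a mean Ct limit of 32 the assays at least 2-fold lower became 4, with these 2 added. No other assay outside the counted set differed 2-fold.

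Ratios of the remaining counted assays (99.2%) lay between -0.80 and 0.87 on the log2 scale. The median over all 489 was 0.04, the central 95% ran from -0.67 to 0.60, and 388 assays (79.3%) were within 0.5 of 0. The SD of 0.40 across assays describes the assays and is no estimate of the error of any of them. No miRNA was below Ct 30 in one sample and at 35 or above in the other.

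**Figure D1:**
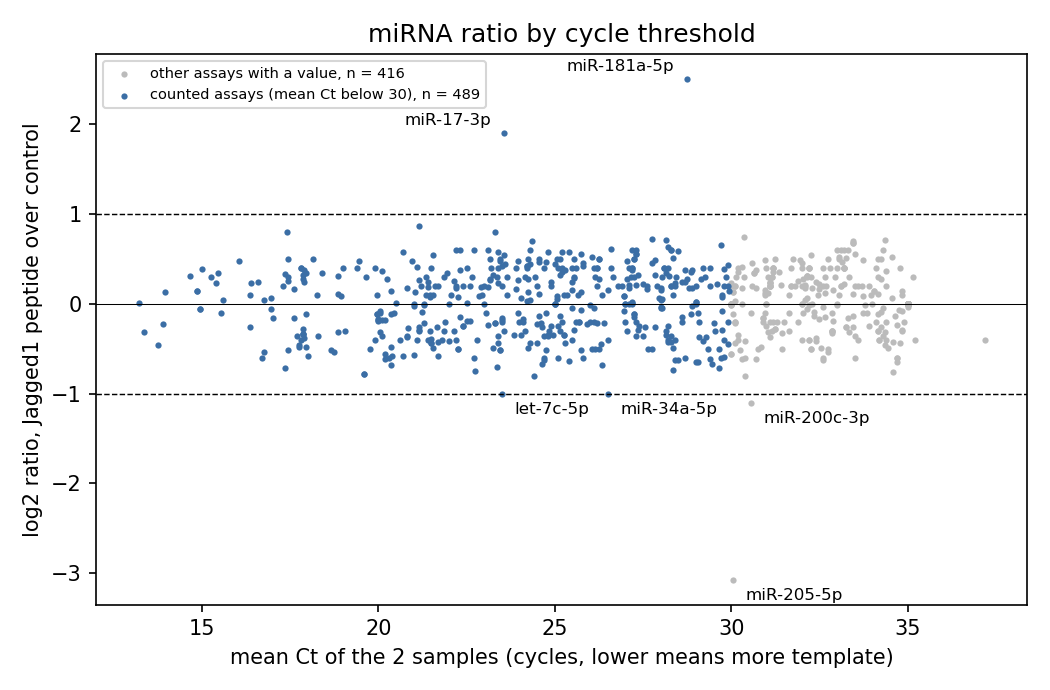
Log2 ratio of Jagged1 over control (y) against the mean Ct of the 2 samples (x, cycles) for 905 assays, 1 point per assay, with the 489 counted assays in blue and the other 416 in grey; dashed lines mark a 2-fold difference. The 6 labelled miRNAs lie on or beyond the dashed lines, from miR-205-5p at -3.07 to miR-181a-5p at 2.5, and all others lie between them.

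Epithelial miRNAs differed among themselves. In the list of miR-205 and miR-203, miR-205-5p was lower while miR-205-3p had a log2 ratio of 0.00 and miR-203a, a differentiation-associated miRNA of the epidermis, one of 0.40. Of the 9 miR-200 family assays, 6 were below Ct 35 in both samples and 4 were in the counted set, of which 0 reached a 2-fold difference. The other 3, miR-141-3p, miR-200b-3p and miR-429, stood at the ceiling of 35 in both samples, where no difference can be seen. miR-200a-5p had a log2 ratio of 0.60, and miR-200c-5p and miR-141-5p had -0.30 each. All values of miR-200a-5p are identical to those of miR-524-3p in the chromosome 19 cluster, so they may not be separate measurements. The family's median was -0.17, at the 28.2 percentile of random lists, and -0.05 from raw Ct. For miR-200a-3p the sources disagree: the normalized values give -0.05, the raw Ct gives 0.20 and the authors' deposited table gives 0.14. The cluster of miR-221 and miR-222, which represses CDKN1B, had 1 counted member, miR-222-3p, with a log2 ratio of 0.19. In the cluster of miR-183, miR-96 and miR-182 no assay was counted, and miR-96-5p had 0.70 at a Ct of 33.8 and 33.1.

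In the proliferation-associated miR-17 cluster and its paralogs, 1 of 10 counted assays was at least 2-fold higher (miR-17-3p) and 0 were 2-fold lower. miR-106b-3p had a log2 ratio of 0.60 and miR-19b-3p one of -0.64. The list median was 0.23 at the 89.4 percentile of random lists. With miR-19b-1-5p (0.40), an arm whose name carries a locus number, it was 0.37 over 11 assays at the 98.9 percentile. Over the 17 assays below Ct 35 in both samples it was 0.10 (59.0 percentile), and over all 22 with a value 0.03. In the let-7 family 1 of 11 counted assays was 2-fold lower (let-7c-5p) and 0 were higher. let-7e-5p had -0.62 and let-7a-3p had -0.44, and the family median was -0.20 (12.3 percentile). The miR-15 and miR-16 family, which represses cyclins and BCL2, had 0 of 8 counted members 2-fold apart. Its median was -0.25 at the 3.23 percentile, and -0.30 over 9 assays at the 1.52 percentile with miR-16-1-3p (-0.52) added, with miR-195-5p at -0.50, miR-195-3p at -0.44 and miR-424-3p at 0.60. The family of miR-99, miR-100 and miR-125 had a median of -0.33 over 6 counted members (5.80 percentile), with miR-99b-3p at -0.78 and miR-125a-3p at -0.56. The Ct and normalized values of miR-99b-3p are identical to those of miR-507 on another list, so the 2 may not be separate measurements.

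The list of miRNAs described as repressors of Notch receptors, their ligands or HES genes had 10 counted members. Of these, 1 was 2-fold lower (miR-34a-5p), 0 were higher and 9 were between, and the median was -0.20 (7.22 percentile). It was -0.05 over the 4 that are known dominant arms or are named without an arm (miR-1 and miR-206). miR-199b-5p had a log2 ratio of -0.68, and miR-34a-3p had 0.50. miR-200c-3p, also on this list, lay outside the counted set. In the family of miR-34 and miR-449 1 of 10 counted members was 2-fold lower, and the median was 0.01 (49.5 percentile). It was -0.45 over the known dominant arm miR-34a-5p and miR-449a, which is named without an arm. In the miR-181 family 1 of 4 counted members was 2-fold higher (miR-181a-5p). The others were miR-181c-3p at 0.57, miR-181a-3p at -0.01 and miR-181d-5p at -0.49. The family median was 0.28 (90.5 percentile), and 0.00 over the 5 members below Ct 35 in both samples. It was 1.005 over the 2 arms known to dominate. With a mean Ct below 28 it was -0.01 over 3 members, and below 25 it was -0.25 over 2.

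Among miRNAs induced by NF-kB and inflammatory signalling, 0 of 6 counted members were 2-fold apart, and the median was -0.10 (27.8 percentile). miR-132-5p had -0.50, and miR-155-3p, outside the counted set, had -0.62. The miR-30 family (median 0.36, 89.2 percentile, 4 members) and the list of miR-130, miR-301, miR-148 and miR-152 (0.30, 93.2 percentile, 7 members) had 0 members 2-fold apart, with miR-30b-3p at 0.63 and miR-130b-5p at 0.58. Over all assays with a value their medians were 0.00 (9 assays) and 0.10 (11 assays). The HOX-cluster miRNAs miR-10 and miR-196 had a median of 0.01 over 6 counted members (54.9 percentile), and -0.12 with plate medians at 0. The list of miR-26, miR-101 and miR-107 had a median of 0.00 over 3 (55.1 percentile), with miR-26b-3p at -0.44. The hypoxia-induced miR-210-3p had a log2 ratio of -0.20 at a Ct of 31.2 and 31.4. In the clusters of miR-23, miR-27 and miR-24 the single counted member, miR-27a-3p, had 0.34. The miR-29 family, which represses collagens, had 2 counted members by the naming rule, miR-29a-3p at -0.40 and miR-29c-5p at -0.20. With miR-29b-1-5p (-0.30) the median of 3 was -0.30 at the 15.6 percentile.

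Markers of other cell types showed no member 2-fold apart in any list. The fibroblast list of miR-199 and miR-214 had the lowest median, -0.68 over 3 counted members (0.26 percentile), with miR-214-3p at -0.70, miR-199b-5p at -0.68 and miR-199a-5p at 0.40. With plate medians at 0 it was -0.45. With miR-214-5p (0.10), which lies outside the counted set, the median of the 4 members was -0.29, at the 6.41 percentile of random lists drawn from all assays below Ct 35 in both samples and so inside the central 95%. Over the counted members it was 1 of 23 lists outside the central 95% of random lists, where chance alone would place 1.15. The mesenchymal miR-143 and miR-145 had a median of -0.24 (11.7 percentile), with miR-145-5p at -0.46 and miR-143-3p at 0.11. Medians were 0.20 for blood cell miRNAs (3 members, 64.0 percentile), 0.25 for striated muscle (4 members, 78.3 percentile, 0.02 with plate medians at 0) and 0.33 for neuronal miRNAs (4 members, 91.1 percentile). miR-223-5p of myeloid cells had 0.48, miR-133a-3p of muscle 0.47 and miR-128-3p of neurons -0.50. The endothelial miR-126-5p had -0.26 and miR-126-3p 0.25. The hepatic miR-122-5p had 0.18 and miR-122-3p -0.36, both outside the counted set.

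Large genomic clusters had no member 2-fold apart. The imprinted DLK1-DIO3 cluster on chromosome 14 had a median of 0.04 over 21 counted assays (38.7 percentile), with miR-379-3p at 0.60 and miR-485-5p at -0.60. The placental cluster on chromosome 19 had a median of 0.10 over 11 (60.0 percentile), with miR-524-3p at 0.60 and miR-520g-3p at -0.51, and turned to -0.10 over the 8 assays with a mean Ct below 28. All values of miR-524-3p are identical to those of miR-200a-5p on another list. The testis-associated cluster on chromosome X had a median of -0.30 over 7 (7.4 percentile), with miR-507 at -0.78, whose values are identical to those of miR-99b-3p, and miR-510-5p at -0.63. Over the 10 assays below Ct 35 in both samples it was -0.16 (15.97 percentile), and over all 12 with a value -0.03. That list also holds miR-511-5p (0.20), whose gene lies on another chromosome. The embryonic miR-302 and miR-371 list had a median of 0.07 over 7 (50.1 percentile), with miR-367-5p at -0.60, and 0.32 over the 4 assays with a mean Ct below 25. The primate miR-548 family had a median of 0.22 over 9 (86.0 percentile), with miR-548i at -0.60 and miR-548b-5p at 0.50. It turned to -0.23 over the 4 assays named without an arm (miR-548i, miR-548p, miR-548q and miR-548v).

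**Figure D2:**
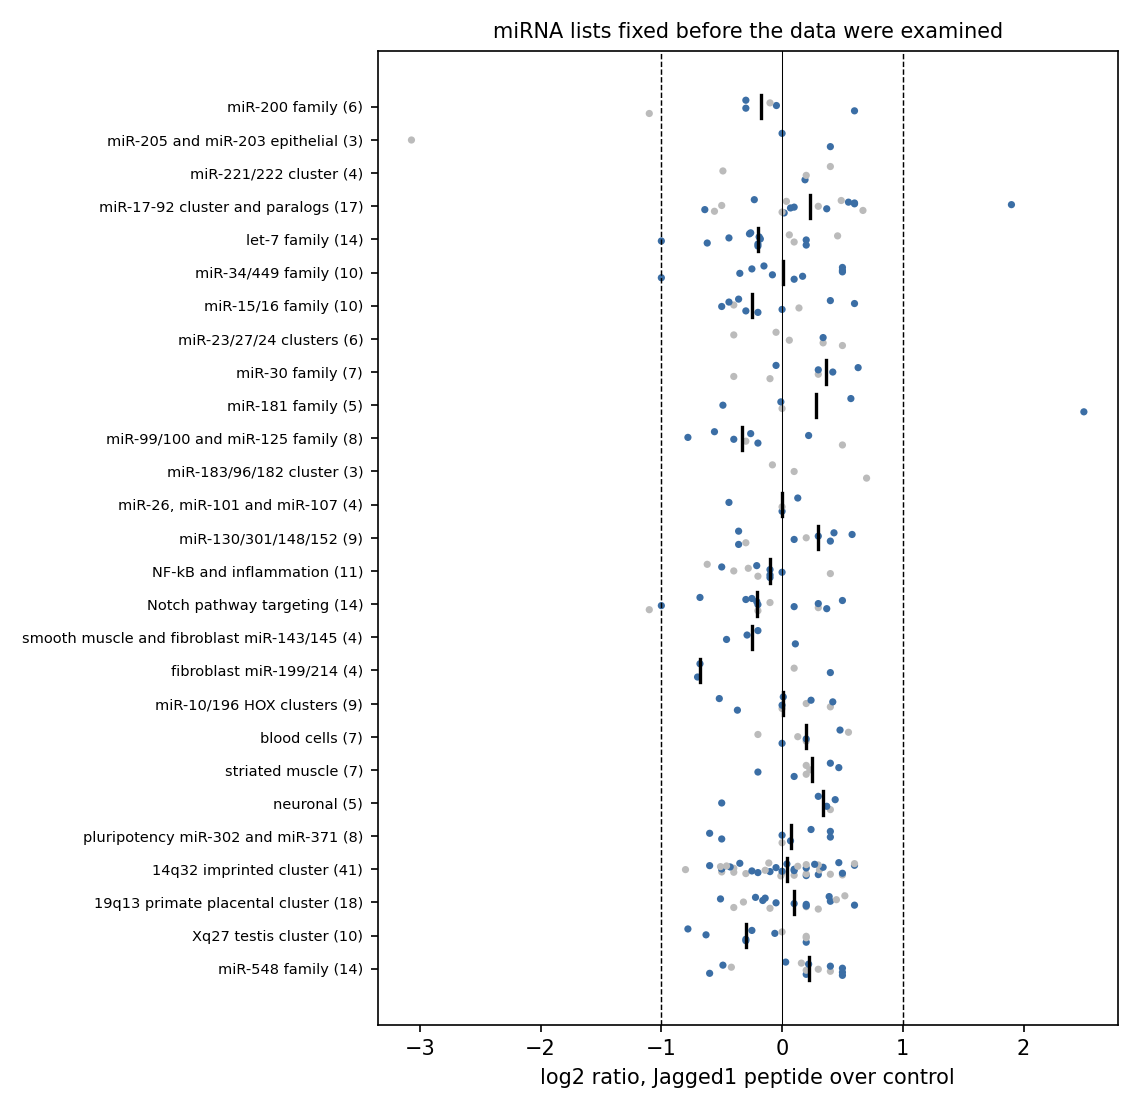
Log2 ratio of Jagged1 over control (x) of the assays below Ct 35 in both samples, by list (y, number of assays in parentheses), 1 point per assay, blue for counted assays and grey for the others; black bars are medians of lists with at least 3 counted assays and dashed lines mark a 2-fold difference. List medians lie between -0.68 and 0.36, and the points on or beyond the dashed lines are those of miR-205-5p, miR-200c-3p, let-7c-5p, miR-34a-5p, miR-17-3p and miR-181a-5p.

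For 5 of the 6 miRNAs at least 2-fold apart the other arm of the hairpin also had a value, and none of these arms was 2-fold apart. miR-205-3p had a Ct of 21 in both samples, beside the log2 ratio of -3.07 of miR-205-5p. miR-181a-3p had a Ct of 21.3 in both samples, and its log2 ratio was -0.01. miR-181a-5p comes from 2 hairpins, and the partner arm of the other one, miR-181a-2-3p, stood at the ceiling of 35 in both samples, where no difference can be seen. miR-17-5p had a log2 ratio of 0.37, miR-34a-3p one of 0.50 and miR-200c-5p one of -0.30. miR-34a-3p thus lay on the other side of 0 from miR-34a-5p.

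**Figure D3:**
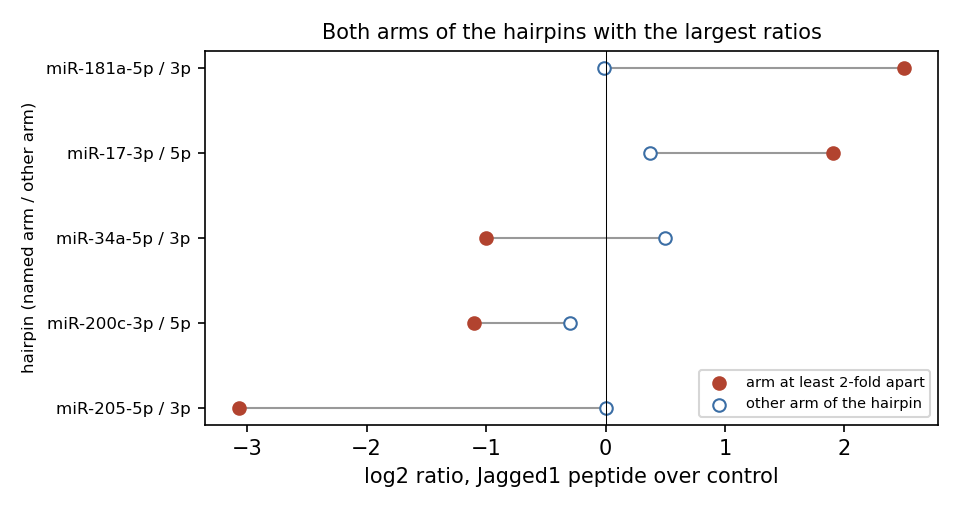
Log2 ratio of Jagged1 over control (x) of the miRNA arm at least 2-fold apart (filled) and of the other arm of its hairpin (open) for 5 hairpins (y), with miR-181a-3p standing for 1 of the 2 hairpins of miR-181a-5p; each point is 1 assay in 1 pair of samples, with no error estimate. The filled points lie from -3.07 (miR-205-5p) to 2.5 (miR-181a-5p) and the open points from -0.30 to 0.50.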

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

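Leaving out whole-number Ct values, keeping only known dominant arms and names without an arm, adding arms with a locus number and taking list members below Ct 35 were chosen after the data were seen. Normalization to reference RNA wells was not run. No replicate, reference well or repeated well was analysed here, so these settings change the processing of the same 2 samples and say nothing about biological spread. Under the 5 other normalizations (median of all counted assays at 0, median per plate at 0, mean of the 50 assays of lowest Ct, raw Ct and the authors' fold table), 2 assays stayed at least 2-fold higher and 2 at least 2-fold lower, and the median of all counted assays stayed between 0.00 and 0.10. Raw Ct and the authors' fold table give nearly the same ratios by construction, since the reference was equal in both samples. Setting the median of all counted assays at 0 shifts each ratio by only 0.04. Little of this stability was therefore open to change. Plate medians ran from -0.23 to 0.26, and of the 6 miRNAs at least 2-fold apart miR-34a-5p moved furthest, to -1.20 with plate medians at 0. miR-205-5p stayed between -3.14 and -3.07, miR-181a-5p between 2.46 and 2.5 and miR-17-3p between 1.84 and 1.90. The Ct limit mattered more, by construction, since it decides which assays are counted: the lower count was 4 with a mean Ct below 32 or with no filter and 1 below 25, and the higher count was 1 below 28 and 1 below 25. At 1.5-fold the counts were 21 higher and 31 lower, and at 4-fold 1 and 0. Leaving out assays with a whole-number Ct in either sample left 1 higher and 0 lower. Of 258 alternative list medians, 238 stayed within 1 SD of the random medians and 20 moved further. Which lists lie outside the central 95% of random lists depends on the members: 1 of 23 (fibroblast miR-199 and miR-214) as counted, 3 of 24 with arms carrying a locus number (that list and those of miR-17 and of miR-15 and miR-16), and 0 of 27 over assays below Ct 35 in both samples, where the fibroblast list stood at the 6.41 percentile. No paired analysis was possible because there is 1 sample per treatment. At Ct 35 a 2-fold loss could not be seen in the 160 assays held there in both samples.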

Other observations

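The tests of ratios across arms, and of ratios and Ct across neighbouring genes, were set before their results were seen; the tests of shifted names, of whole-number values and of the partner arms of the largest ratios were chosen only after the results were seen.

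Ratios of miRNAs from one hairpin or one genomic cluster were no closer to each other than permuted ratios. The 52 hairpins with both arms among the counted assays had a median absolute difference between arms of 0.48 on the log2 scale, at the 94.5 percentile of 10000 permutations (permuted median 0.38). The 151 pairs of counted assays from miRNA genes within 10 kb of each other had a median absolute difference of 0.40, at the 67.1 percentile. These values give no sign that co-transcribed miRNAs move together, and leave it open, since whether each assay measures the arm it names was not established.

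The largest ratios were not shared with the partner arm. For miR-205-5p, miR-181a-5p, miR-17-3p, miR-34a-5p and miR-200c-3p the median absolute log2 ratio was 1.9, while the other arm, signed by the direction of the named arm, had a median of 0 (SD 0.34 over the 5 hairpins, with 1 of the 2 hairpins of miR-181a-5p, since the partner arm of the other was at the ceiling of 35). A change in the shared precursor would move both arms alike only if they are equally stable and each assay measures the arm it names, which was not established, so it stays open. Regulation after processing of the precursor, an effect of the Jagged1 peptide on single arms, or scatter of single PCR wells may each account for it, and none of these was tested, since each sample has 1 value.

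In 37 of 76 hairpins with unequal Ct (48.7%, exact 95% interval 37.0% to 60.4%, counting error only), the arm that dominates in most human tissues, by a list drawn up from general knowledge, had the lower Ct, so Ct did not follow known dominance. Genes within 10 kb had closer mean Ct than permuted values (571 pairs, median difference 4.6 against 5.55 cycles, 0.465 percentile, and 1.68 percentile when permuted within plates). This does not decide whether all names are unrelated to their values, since the permutations ignore well order. Genes of 1 cluster can sit in adjacent wells with equal Ct, such as miR-513b-5p and miR-513c-5p, at 35 in both samples. Some normalized control levels also recur in the same well order under other names. The levels 0.00213729, 0.00118574 and 0.00054555 belong to miR-124-3p, miR-92a-3p and miR-23a-3p. They recur for miR-345-5p, miR-219a-2-3p and miR-554, and for miR-34b-3p, miR-34b-5p and miR-1321. These levels open longer runs of wells that share most control levels in order, up to 33.3589 for miR-191-5p, miR-551b-3p and miR-513c-3p. Some pairs in the runs share the Jagged1 level as well, such as miR-92a-3p and miR-219a-2-3p (0.000804288). Members of the lists above lie in these runs, among them miR-195-5p, miR-30d-5p, miR-485-5p and miR-510-5p. Whether such values belong to their names stays open. Names shifted along the wells stay open: the highest share over 24 shifts of up to 12 wells was 51.4% (exact 95% interval 39.2% to 63.6%), but unequal assay efficiency, which was not measured, could keep the share low under the right names as well. Off-target amplification under SYBR Green may also remain. miRNAs numbered from 3000 had a median mean Ct of 28.6 with 31.9% below 25, against 29.35 and 27.1% for numbers up to 500, which bears on this without deciding it, and no biological explanation was tested.

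Whole-number Ct values were frequent. With values of 35 left out, 18.8% of control and 26.8% of Jagged1 values were whole, where evenly spread last digits give 10%, and 41.4% of 734 assays were whole in at least 1 sample, where 19% would follow. This argues against the ceiling at 35 as the whole cause. Ct recovered to 2 decimals from the normalized table was whole within 0.005 cycles for 15.9% of control and 24.6% of Jagged1 values. On plates 2 and 3, however, ratios from the normalized values equal those from raw Ct with 1 decimal. On other plates many levels of 1 sample also correspond to a Ct with 1 decimal. Examples are the Jagged1 level of miR-1322 on plate 6 (68.5935, Ct 13.9) and the control level of miR-196a-3p on plate 9 (111.43, Ct 13.2). Recovered Ct cannot test rounding at such values, so these pooled shares do not decide whether rounding of the raw table for display played a part. The cause was not determined and no biological explanation was tested, and let-7c-5p and miR-34a-5p have whole-number Ct in both samples (as do 33 of 734 assays) and miR-181a-5p and miR-200c-3p in 1.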
